A study of Homo sapiens with 13 samples.

How the data were processed

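The series holds 13 CUT&RUN libraries of HT29 cells, and peak lists of 9 were analysed: 3 of STAT3 with DMSO, 4 of STAT3 with ISX9, and 1 each of FLAG-CoREST2 from a fixed and a native preparation. The other 4, IgG and CoREST2 knockdown controls, are not analysed here, so no background measured in control samples stands beside the values. Per the labels' protocols, a commercial kit with protein A/G-tagged nuclease was used and libraries were made with a ligation-based kit. Per the submitters' processing notes, FastQC 0.12.1, Bowtie2 2.5.1, MACS2 2.2.7.1 and hg38 were used. Each list belongs to 1 library.

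The deposited lists are in narrowPeak layout. The deposited score is 10 times the −log10 of the p-value in 9 of 9 lists, the deposited fold enrichment is a linear ratio over the local background, and the p-value and q-value are deposited as −log10. These are the authors' values, used only to describe, rank or filter peaks within a list. From the values, STAT3 lists reach down to a −log10 p of 3.31 to 3.35 and CoREST2 lists to 1.30, so the lengths of the lists of the 2 proteins cannot be compared. Read depth is unknown. The fold and p of a peak fix the whole number of fragments at its summit under the formulas of MACS2, and 100% of the peaks gave such a number within 0.001 on −log10 p. On simulated peaks 100% were recovered. A peak built on 3 or 4 fragments can be lost or gained by counting error alone.

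Peaks on chromosomes 1 to 22, X and Y were used. STAT3 peaks of the 7 libraries were merged where they overlapped by at least 1 base. Regions present in all libraries of 1 treatment and none of the other were counted, and regions in 3 to 6 libraries were tested by Fisher's exact test with Benjamini-Hochberg adjustment. Group means were compared by exact permutation over 35 splits of the 7 libraries, two-sided, with a smallest p of 0.0286. Shares were compared with the same peaks moved 10 kb to each side, by an exact sign-flip permutation test over 7 libraries, with a smallest p of 0.0156. In the self-test, 200 regions were planted in every ISX9 list and no DMSO list. Of these, 100% were recovered, and 0 were called where none was planted. Recovery was nearly certain with such full presence, so the self-test checks the counting and gives no power to detect weak peaks.

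Gene positions came from a RefSeq table of the GRCh38.p14 assembly, which shares the coordinates of hg38. It gives no strand, so the distance to a transcription start planned for the tests was replaced by the distance to either end of a protein-coding gene. All 273 entries of the 12 gene lists matched. The members per treatment of some lists are not reported here. The lists are JAK-STAT pathway, STAT3 targets, LSD1 and CoREST complexes, enteroendocrine, goblet and mucin, absorptive enterocyte, Paneth, tuft, stem cell and Wnt, secretory fate and Notch, neuronal REST targets, and housekeeping. Tests of STAT motifs were planned and not run, because no genome sequence was used here.

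Fewer than 1000 CoREST2 peaks of either list had q at most 0.05, so the rule fixed in advance took the 20000 with the highest −log10 p. Many were tied there, 21957 in the fixed and 5602 in the native list, and ties were ordered by fold and then at random with a fixed seed. That order was chosen after an arbitrary order had been tried on the data, and the report and the closing section give other orders. A region was recurrent in at least 2 of 3 DMSO or 3 of 4 ISX9 libraries.

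Before the data were examined, the samples, tests, gene lists, alternatives and the rule for named genes were fixed. The rule names up to 10 regions gained and 10 lost, 10 regions in all 7 libraries, up to 4 members of each list with a STAT3 summit in at least 2 libraries, 10 recurrent regions overlapping both CoREST2 lists, and 15 genes in any case. Alternatives were a stricter q of 0.001, lists of equal length, all contigs, other overlap rules and distances, other CoREST2 sets and controls, leaving out each library, and a replicate block. The data were explored before the final analysis was written, and alternatives added then are named as chosen after seeing the data. Same-numbered libraries of the 2 treatments had correlations of 0.105, 0.056 and 0.397 over regions in 2 or more libraries, so the numbers were not taken to pair them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.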

Results

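CUT&RUN peak lists were analysed from HT29, an established human colorectal cancer cell line. In CUT&RUN an antibody directs micrococcal nuclease to a chromatin protein, and the DNA fragments that it releases are sequenced. The transcription factor STAT3 was profiled in 3 libraries from cells given the vehicle DMSO and in 4 libraries from cells given ISX9 (isoxazole-9), a small molecule. FLAG-tagged CoREST2, a corepressor encoded by RCOR2 that partners the histone demethylase LSD1 (KDM1A), was profiled in 1 fixed and 1 native preparation. The series concerns LSD1, CoREST2, STAT3 and enteroendocrine differentiation. The comparisons ask where STAT3 peaks lay with and without ISX9, and whether they coincided with CoREST2 peaks. Nothing in the labels says that replicates came from separate cultures, so p-values over libraries measure their spread, which may be technical. Fisher's exact tests of gene lists and of region locations count genes or regions as units, so their p-values measure no such spread. Coordinates are in hg38.

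The STAT3 lists held between 1106 and 1936 peaks on chromosomes 1 to 22, X and Y. The DMSO lists averaged 1610 ± 443 peaks (SD, n = 3) and the ISX9 lists 1425 ± 239 (SD, n = 4). The difference of -184 peaks (ISX9 minus DMSO, as in all differences given here) was smaller than the SD of the DMSO lists (exact permutation test, two-sided, p = 0.457). It ran from -436 without DMSO 2 to -21.25 without DMSO 1. Among libraries numbered 1 and 2 the difference was 28.5 peaks (n = 2 and 2), and among those numbered 3 and 4 it was -486 (n = 1 and 2). Most peaks rested on very few fragments. In the STAT3 lists, 85.0% to 88.7% of the peaks had a summit pileup of 3 or 4 fragments, and between 8 and 70 peaks per list had q at most 0.05. A count of 3 has an exact 95% Poisson interval of 0.619 to 8.77, which covers counting error only. Read depth is unknown.

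**Figure D1:**
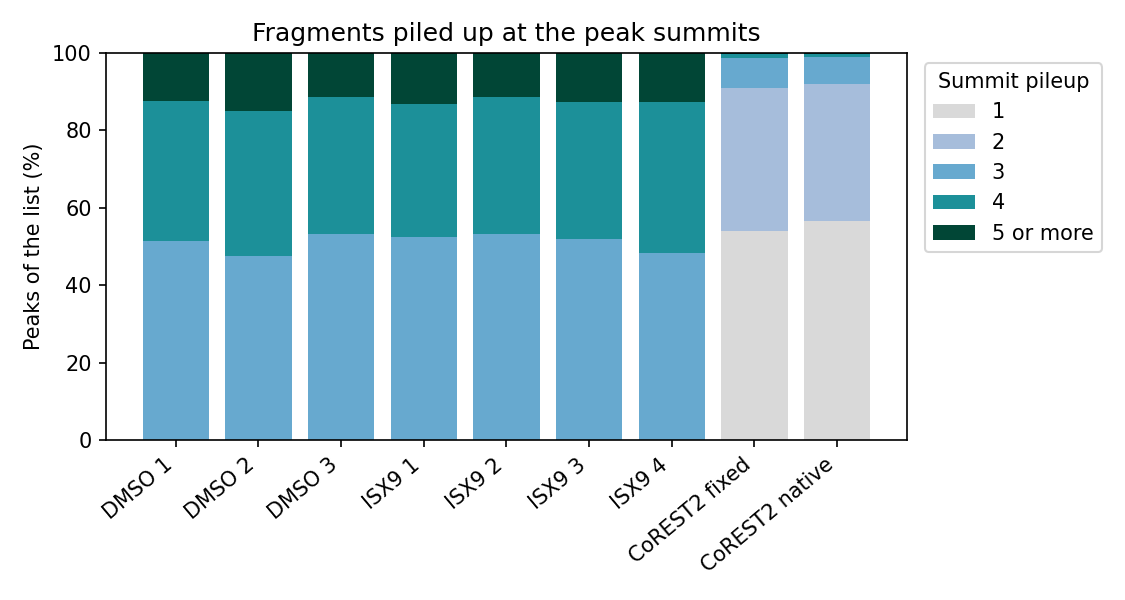
Share of peaks in each list (y axis, percent) by the number of fragments piled up at the summit (colours), for each library (x axis). Pileups of 3 or 4 make up 85.0% to 88.7% of the STAT3 peaks, and pileups of 1 or 2 make up 91.0% of the fixed and 92.1% of the native CoREST2 peaks.

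Libraries with a higher background had longer STAT3 lists, a relation noticed in the data. Across the 7 libraries, peak number and the most frequent background pileup were correlated (Pearson r = 0.903, permutation p = 0.0099; Spearman rho = 0.929, permutation p = 0.0067; adjusted p = 0.0139 for both, 3 coefficients computed). Without the 2 libraries farthest from the median background, DMSO 2 and ISX9 2, r was 0.932 (permutation p = 0.025). Within the sets of replicate numbers, which hold 4 and 3 libraries, all 9 pairs of libraries had the same order in both measures. With values centred on their set, r was 0.981 (permutation within sets, p = 0.0139, adjusted p = 0.0139), a test added after seeing the data. The background was recovered from fold and p, and may in part stand for the unknown read depth. Every STAT3 list held only peaks with a pileup of 3 or more. More positions reach 3 by counting alone where the background is higher, so the relation may be built into peak calling.

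**Figure D2:**
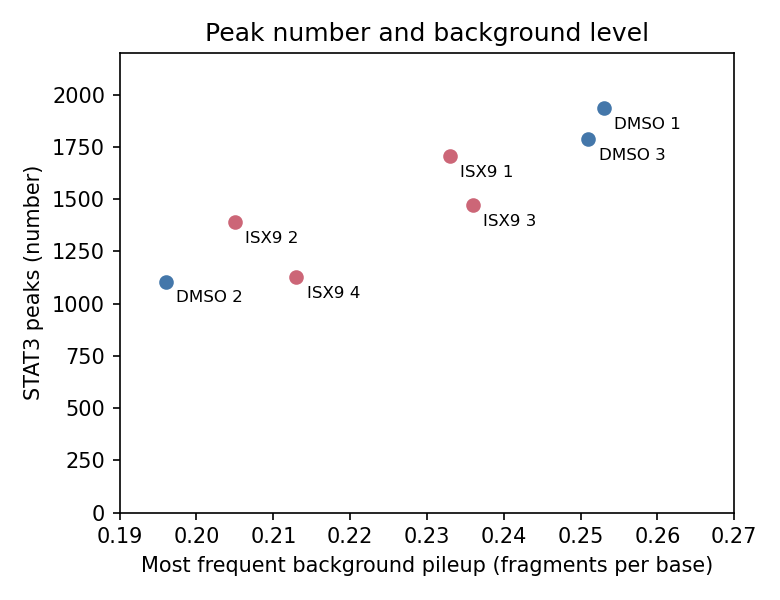
Number of STAT3 peaks (y axis) against the most frequent background pileup in fragments per base (x axis), 1 point per library, DMSO in blue and ISX9 in red. The list with the lowest background, 0.196, has 1106 peaks and the list with the highest, 0.253, has 1936.

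Few STAT3 regions were found in more than 1 library. Merging the 7 lists gave 10347 regions, of which 10227 were in 1 library, 83 in 2 and 37 in 3 or more, and none was in all 7. The 3 regions in 6 libraries, named after their values were seen, lay outside genes. They were on chromosome 4 at 49149167 to 49149795, 87.4 kb from CWH43, on chromosome 8 at 43239660 to 43240091, 37.0 kb from HGSNAT, and on chromosome 5 at 49602350 to 49602879, 794 kb from EMB. Each was in 3 DMSO and 3 ISX9 libraries. Where present, summit pileups were 151 to 272 for the region on chromosome 4. They were 30 to 39 for that on chromosome 8 and 111 to 146 for that on chromosome 5. The highest −log10 q was 11.1, 3.12 and 0.637 in the same order. The region on chromosome 5 thus had q at most 0.05 in no library, despite its high pileups. No repeat filter was run, so repeated sequence is not excluded. A region inside ART1 (chromosome 11, 3653904 to 3654690) was in 2 DMSO and 2 ISX9 libraries. These were DMSO 1, DMSO 2, ISX9 1 and ISX9 2, and no library numbered 3 or 4 had it.

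No region was in all ISX9 libraries and absent from all DMSO libraries. In the opposite direction there was 1, on chromosome 13 at 16725622 to 16725983, 2.45 Mb from TUBA3C, a tubulin gene. Its highest −log10 q was 1.13, so it had q at most 0.05 in no library. A region inside TPCN2, which encodes a lysosomal cation channel (chromosome 11, 69076862 to 69077393), was in 3 of 4 ISX9 and 0 of 3 DMSO libraries, and is named here after its values were seen. Its Fisher's exact p was 0.143 and its highest −log10 q 0.156. It was 1 of 2 regions with this presence, and the other lay 1.397 Mb from the nearest protein-coding gene, with the same p and a highest −log10 q of 2.60. Among the 37 regions tested by Fisher's exact test, 0 passed after Benjamini-Hochberg adjustment and 1, the TUBA3C region, had an unadjusted p under 0.05 (exact p = 0.0286). That is the smallest p this design allows, and a single region at that p cannot pass the adjustment over 37. The count of regions in all DMSO and no ISX9 libraries was 7 without DMSO 3 and 3 without DMSO 2 or ISX9 3. It was 2 without DMSO 1 or ISX9 1. The count in the ISX9 direction was 1 without ISX9 1 or ISX9 4. Leaving out a library loosens the rule for such regions, so these rises say nothing about stability.

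STAT3 lists of the same treatment were not detectably closer to each other than lists of different treatments. The mean Jaccard index, the share of bases common to 2 lists, was 0.382% within and 0.459% between treatments, a difference of -0.0777 percentage points (exact permutation test, one-sided, p = 0.771, n = 7). Lists of 1 treatment shared between 3 and 23 regions, and lists of different treatments between 3 and 32. Lists from libraries numbered 1 and 2, or from those numbered 3 and 4, shared between 14 and 32 regions, and lists across these sets shared between 3 and 12. The peak names of the former set carry the tag IgG1 and those of the latter do not. The Jaccard index was 0.645% within and 0.262% between these sets, a division noticed in the data (exact permutation p = 0.0286, one-sided, the smallest of the 35 splits).

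**Figure D3:**
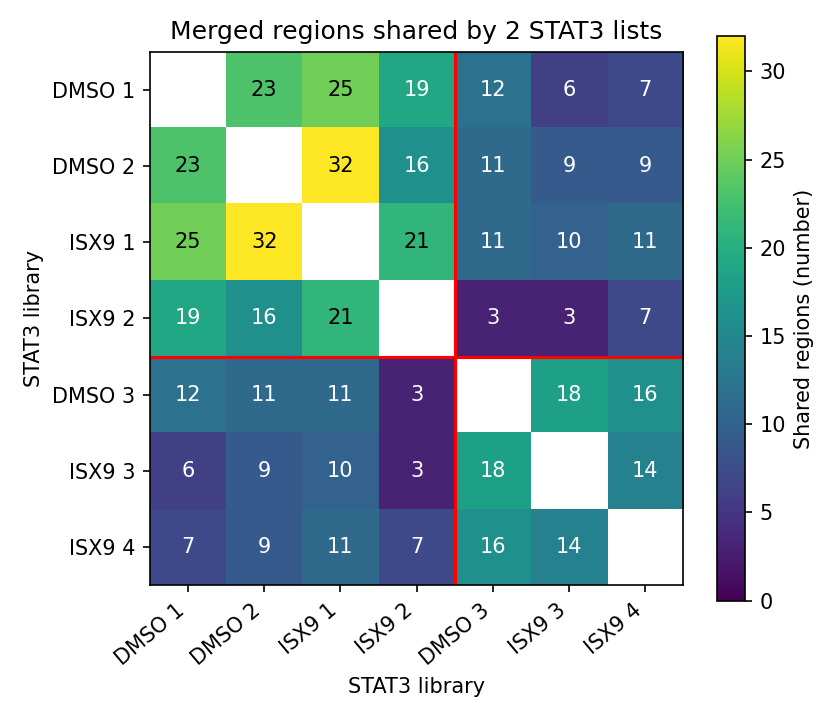
Number of merged regions shared by each pair of STAT3 libraries (both axes; colour and figures give the number). Red lines part libraries numbered 1 and 2 from those numbered 3 and 4. Pairs within these sets share 14 to 32 regions and pairs across them 3 to 12.

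Genes of the 12 lists fixed before the data were examined had STAT3 summits about as often as other genes. Of the 264 listed genes, 40 had a summit within 10 kb of a gene end in any library, against 15.2% of all protein-coding genes (3040 of 20037), and 4 had one in 2 or more libraries. L1CAM, a neuronal adhesion gene repressed by REST, had one in 3 libraries (DMSO 1, DMSO 2 and ISX9 2). CEACAM1, an enterocyte adhesion gene, had one in DMSO 1 and ISX9 1. CREB3L1, a transcription factor of secretory cells, had one in DMSO 1 and DMSO 2, and TUBB3, a neuronal tubulin, in ISX9 2 and ISX9 3. For each of these 4 genes the peaks of different libraries did not overlap. Of the 47 summits near listed genes, 43 had a pileup of 3 or 4 fragments, and 0 had q at most 0.05.

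Among the genes named in advance, MUC2, the main secreted intestinal mucin, was the only one of 15 with a summit within 10 kb. It lay 2.76 kb away in DMSO 3 (chromosome 11, 1113171 to 1113544), with a pileup of 5. The nearest STAT3 summit in any library was 11.2 kb from MYC, 97.1 kb from SOCS3, 99.8 kb from STAT3 and 75.7 kb from BCL3, all known STAT3 targets. For the enteroendocrine genes it was 12.5 kb from NEUROG3, 48.8 kb from NEUROD1, 153 kb from INSM1 and 209 kb from CHGA. It was 36.2 kb from ATOH1 and 33.6 kb from HES1, which act on secretory fate, and 28.4 kb from the stem cell marker LGR5. It was 325 kb from KDM1A, 326 kb from RCOR1 and 146 kb from RCOR2.

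The goblet and mucin list had 2.33 ± 1.15 members with a summit within 10 kb per DMSO library (SD, n = 3) and 0.5 ± 0.577 per ISX9 library (SD, n = 4; exact permutation p = 0.0857, adjusted p = 0.857 over the 12 lists). The members in DMSO were BCAS1, CREB3L1, MUC2, MUC5AC, MUC12 and SPDEF, and those in ISX9 were TFF1 and ST6GALNAC1. The STAT3 target list had 0.667 ± 0.577 per DMSO library (CCND1 and TWIST1) and 0.25 ± 0.5 per ISX9 library (TNFRSF1A; exact permutation p = 0.486). The JAK-STAT list had 1 ± 1 members per DMSO library (IL22RA1, PTPRT and TYK2) and 0.75 ± 0.957 per ISX9 library (JAK2, STAT2 and STAT5B). For neuronal REST targets the means were 0.667 in DMSO (L1CAM) and 1 in ISX9 (GRIN1, L1CAM and TUBB3). Absorptive enterocyte genes had means of 0.333 (CEACAM1) and 0.75 (ANPEP, APOA4 and CEACAM1), and stem cell and Wnt genes 0.333 (ASCL2) and 0.5 (BMI1 and NOTUM). Paneth genes had 0 and 0.25 (PLA2G2A), secretory fate and Notch genes 0 and 0.25 (LFNG), and housekeeping genes 0.667 (GAPDH and RPLP0) and 0. Between treatments 0 of the 12 lists passed the exact permutation test, before or after adjustment over the 12 lists. A single list cannot get an adjusted p under 0.343 here. Recurrent regions lay within 10 kb of 2 protein-coding genes in DMSO and 0 in ISX9, none of them listed, so no list could be tested on them.

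Counting regions in at least 1 library instead, 6 of 22 goblet and mucin genes were near a DMSO region, 27.3% against 7.26% of 20037 protein-coding genes (Fisher's exact test, one-sided, p = 0.0039, adjusted p = 0.0472). For ISX9 regions the count was 2 of 22 (Fisher's exact test, adjusted p = 0.917). For all 7 libraries pooled it was 8 of 22 (Fisher's exact test, adjusted p = 0.146).

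STAT3 peaks at gene ends, 1 of which holds the promoter, were few. Of DMSO peaks, 4.01% ± 0.271 (SD, n = 3) had the summit within 1 kb of an end of a protein-coding gene, against 3.81% ± 0.665 of ISX9 peaks (SD, n = 4), a difference of -0.206 percentage points (exact permutation p = 0.657). It was -0.333 among libraries numbered 1 and 2 and -0.198 among those numbered 3 and 4. It ran from -0.531 without ISX9 4 to -0.0456 without ISX9 3, and was 0.0527 in lists of equal length. Over the 7 libraries the share was 3.90%, against 3.56% after moving the peaks 10 kb to each side (exact sign-flip permutation p = 0.344, higher in 4 of 7).

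The CoREST2 lists were long and weak. The fixed list held 670747 peaks and the native list 647558 on the same chromosomes, and 16 and 232 of them had q at most 0.05. A summit pileup of 1 or 2 fragments accounted for 91.0% of the fixed and 92.1% of the native peaks. A count of 1 has an exact 95% Poisson interval of 0.0253 to 5.57. The 4 strongest native peaks lay on nuclear copies of mitochondrial DNA, led by one on chromosome 1 at 631848 to 632967, over the pseudogenes MTCO1P12 and MTCO2P12. The strongest fixed peak was on chromosome 17 at 22521218 to 22521564, 0.817 Mb from KCNJ18. These peaks were chosen by strength after the data were seen. Of the 20000 strongest fixed peaks, 1.11% overlapped one of the 20000 strongest native peaks (exact 95% binomial interval 0.965 to 1.26), against 0.873% after displacement by 10 kb. There is 1 library of each preparation, so this difference has no replicate check. Over all deposited peaks the shares were 19.4% and 19.3%. The difference for the 20000 strongest peaks, 0.2325 percentage points, was 0.105 when an overlap of at least 50% of both peaks was required. It was 0.1075 with ties in the order of the list and 0.254 with all tied peaks taken, settings chosen after seeing the data.

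STAT3 peaks overlapped the 20000 strongest CoREST2 peaks more often than displaced peaks did, by a small margin. For the fixed preparation the share was 0.907% ± 0.143 (SD, n = 7), against 0.679% displaced, higher in 6 of 7 libraries (exact sign-flip permutation p = 0.0312, adjusted p = 0.0417 over 4 tests). For the native preparation it was 1.43% ± 0.373 (SD, n = 7), against 0.962%, higher in 6 of 7 (exact sign-flip permutation p = 0.0312, adjusted p = 0.0417). This is between 12 and 34 peaks per library. All 7 STAT3 libraries were set against the same 1 CoREST2 list per preparation, so these p-values measure no spread of CoREST2 libraries. The differences were 0.228 (fixed) and 0.469 (native) percentage points, and 0.2325 for the 2 CoREST2 lists against each other. Signal that does not depend on the antibody was not excluded, as the IgG libraries are not analysed here. Only 1 recurrent STAT3 region overlapped peaks of both preparations. It lay on chromosome 2 at 164261446 to 164261844, 231 kb from GRB14, an adaptor of insulin signalling. This region was in 1 DMSO and 3 ISX9 libraries, with summit pileups of 4 or 5. Its highest −log10 q was 0.156, so it had q at most 0.05 in no library. With 1 library left out the differences were 0.183 to 0.288 (fixed) and 0.355 to 0.565 (native) percentage points. The test on 6 libraries cannot go under 0.0625 while the 1 library below its displaced value is kept, which was DMSO 1 for the fixed and ISX9 2 for the native preparation. In 11 other settings on all 7 libraries the difference stayed above 0, and the fixed call was kept in 7 and the native call in 6. The native call ended with ties among CoREST2 peaks in the order of the list or with all tied peaks taken (exact p = 0.0938 and 0.109), settings chosen after seeing the data. With STAT3 peaks within 500 kb of a protein-coding gene alone, a setting chosen after seeing the data, the differences were 0.126 and 0.325 percentage points (exact p = 0.0938 and 0.125).

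**Figure D4:**
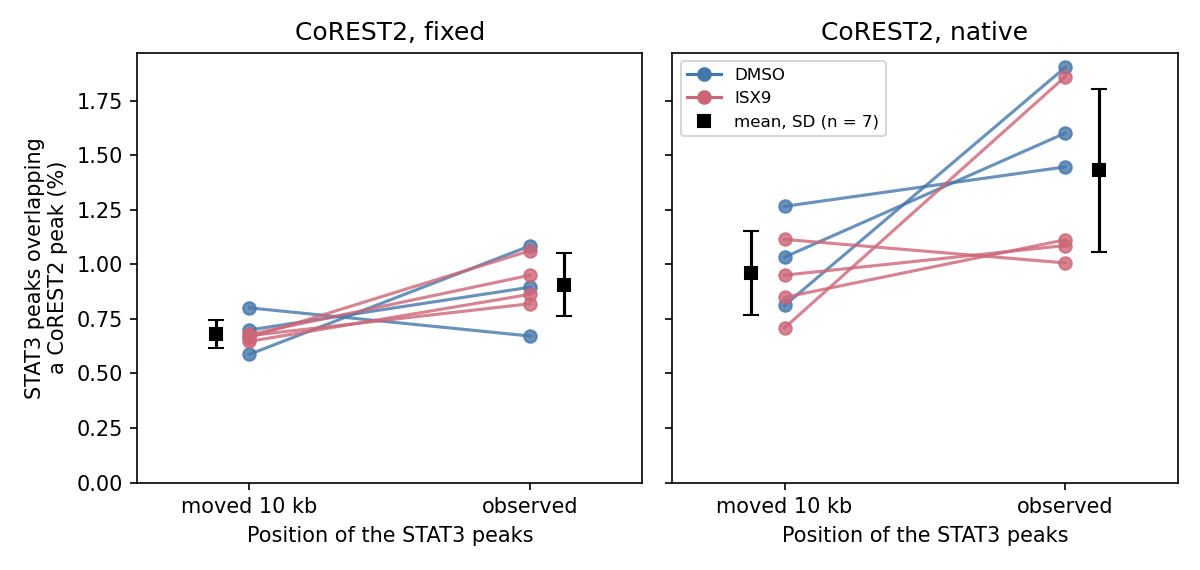
Share of STAT3 peaks that overlap a CoREST2 peak (y axis, percent), observed and after moving the peaks 10 kb (x axis), for the fixed (left) and native (right) preparation. Lines join the values of 1 library and black squares give the mean and SD of 7 libraries, 0.907% against 0.679% on the left and 1.43% against 0.962% on the right.

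No difference in this overlap between ISX9 and DMSO was detectable with these libraries, both set against the same 1 CoREST2 list per preparation. For the fixed preparation it was 0.884% ± 0.207 in DMSO (SD, n = 3) and 0.924% ± 0.107 in ISX9 (SD, n = 4; difference 0.0400 percentage points, exact permutation p = 0.800). Within the libraries numbered 1 and 2 the difference was -0.0371 and within those numbered 3 and 4 it was 0.111. For the native preparation it was 1.65% ± 0.232 in DMSO and 1.27% ± 0.398 in ISX9 (difference -0.384 percentage points, exact permutation p = 0.171), and within the 2 sets it was -0.465 and -0.429. Without ISX9 4 it was -0.582 (exact permutation p = 0.1, the smallest for 3 against 3), and without DMSO 3 it was -0.258. Its direction turned with all CoREST2 peaks (0.438), CoREST2 peaks with q at most 0.05 (0.137) and STAT3 peaks with q at most 0.001 (11.4). The fixed difference turned with all CoREST2 peaks (-1.005), with all tied CoREST2 peaks (-0.024) and without DMSO 1 (-0.0663), among other settings.

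Listed genes seldom had CoREST2 peaks of both preparations within 1 kb of a gene end. MLN, which encodes the gut hormone motilin, was the only one, out of 29 such genes genome-wide. No list passed Fisher's exact test after adjustment, and 1 did before it: the enteroendocrine list, with 1 of 35 genes, had p = 0.0495 (adjusted p = 0.594). The native list alone had a peak within 1 kb of LGR5 and of 4 of 32 STAT3 targets, BCL3, CEBPB, MCL1 and MYC (Fisher's exact test, p = 0.0438, adjusted p = 0.421). The JAK-STAT list had 4 of 26 genes marked in the fixed list alone (Fisher's exact test, p = 0.0089, adjusted p = 0.107), which were IL6R, JAK1, STAT5A and STAT5B. The neighbouring genes STAT5A and STAT5B share 1 peak, while the test counts them as independent.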

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

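Most tests in this part were chosen after the results they bear on had been seen: those of summit pileup, matched share, FLAG overlap and distance to genes, and the split counts for ISX9 regions and for Fisher's test. The split count for DMSO regions was set before its result was seen.

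The share of STAT3 peaks overlapping native CoREST2 peaks stood apart in ISX9 4, at 1.86%, from the other 3 ISX9 libraries, with a gap of 0.876 of the range. Chance alone gives about 1 such value in 20 groups, and 13 measures were looked at. Peaks on the mitochondrial chromosome, which entered no comparison of the report and only the setting with all contigs, had summit pileups of up to 335 fragments in DMSO 3, 463 in ISX9 1, 320 in ISX9 3, 475 in ISX9 4, 536 in the fixed and 555 in the native CoREST2 list. DMSO 1, DMSO 2 and ISX9 2 had no such peak.

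STAT3 peaks were rarely found in a second library: 2.97% ± 0.858 of them were (SD, n = 7), against 0.421% after displacement (exact sign-flip permutation p = 0.0156, the smallest possible). A difference in binding between DMSO and ISX9 cannot be the whole cause, since the best match between 2 libraries of 1 treatment was 2.08% of the shorter list. Peaks with a pileup of 6 or more were matched more often than peaks with a pileup of 3, by 36.2 percentage points on average (exact sign-flip permutation p = 0.0156). This is consistent with most peaks lying at the edge of the background, though peaks in repeated sequence may also have high pileups. It leaves open how many of the single-library peaks are STAT3 sites. Each list was matched against the other lists pooled, so a shared region counts in more than 1 list. The 7 values of both sign-flip tests are therefore not independent, and their p-values may be too small.

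Of the 37 regions in 3 or more STAT3 libraries, 4 lay inside protein-coding genes, 10.8% against 45.1% of regions in 1 library (Fisher's exact test, p = 1.55e-05). Only 5.41% were within 10 kb of a gene end, against 23.9% of regions in 1 library (Fisher's exact test, p = 0.0059). Most of the 37 regions were therefore not STAT3 sites near genes kept in both treatments. Peaks of few fragments seldom reach 3 libraries, so weaker sites of that kind are not excluded. Of the 37 regions, 8 lay near CWH43 on chromosome 4 between 49.1 and 49.2 Mb, 4 near H3-7 on chromosome 1 and 3 near EMB on chromosome 5. The Fisher's exact tests of this paragraph count such neighbours as independent, so their p-values are likely too small. FLAG-CoREST2 peaks overlapped 13.5% of the 37 regions and 1.99% of the regions in 1 library (Fisher's exact test, p = 0.00086), as signal that does not depend on the antibody may do. STAT3 and CoREST2 sharing these sites stays open, as the IgG libraries are not analysed here.

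Other splits of the 7 libraries bear on only 1 of the 3 counts of treatment-specific regions. The splits do not keep to the sets of replicate numbers, whose lists stood apart. For regions in all DMSO and no ISX9 libraries, chance was not excluded: 14 of the 35 splits gave at least the 1 seen, and the highest other gave 3. For regions in all ISX9 and no DMSO libraries, 0 were seen, so all 35 splits reach that count by construction, and the highest other gave 6. The same holds for regions past Fisher's exact test after adjustment, where 0 were seen, all 35 splits reach that count and the highest other gave 0. These last counts say nothing about chance.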

How the results depend on the processing

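Settings on peaks within 500 kb of genes, replicate sets, CoREST2 peaks by q and CoREST2 ties were chosen after the results were seen. Of 202 values, 154 held: tested ones kept direction and side of the threshold, others were equal or near. Of them, 6 repeat the reported setting and 46 are adjusted-test counts at 0, leaving 102. Treatment tests with 1 library left out cannot go under 0.0667, so their side of the threshold was fixed. Overlap with CoREST2 is given as the difference from displaced peaks in percentage points, with exact p, and as ISX9 minus DMSO. With STAT3 q at most 0.001, fewer peaks remained: 0 regions were DMSO-specific, overlap was 3.57 (fixed, p = 0.5) and 18.1 (native, p = 0.125, exact), and ISX9 minus DMSO was -1.04 and 11.4. In lists of equal length the gene-end difference was 0.0527 and native overlap 0.517 (exact p = 0.0938). Blocking by replicate number, with 3 pairs and a smallest p of 0.25, gave 1 ISX9-specific region, overlaps of 0.1996 (fixed) and 0.355 (native, exact p = 0.25 each) and a fixed treatment difference of -0.00634. The block leaves out ISX9 4, and its values equal those without that library. Only its p-values differ, so among the 202 values it repeats that setting. With all CoREST2 peaks, fixed overlap was 1.44 (exact p = 0.0781), native overlap 1.17 (exact p = 0.0312) and the treatment differences were -1.005 (fixed) and 0.438 (native). With the STAT3 summit inside the peak the fixed treatment difference was -0.0934. Regions in at least 1 library gave 1 gene list. Within 500 kb of genes there were 0 DMSO-specific regions, and overlaps were 0.126 and 0.325 (exact p = 0.0938 and 0.125). With CoREST2 q at most 0.05, fixed overlap was 0.0103 (exact p = 1), native overlap 0.15 (exact p = 0.0156), the native treatment difference 0.137 and the fixed-native difference 6.25. The value of 6.25 rests on 1 overlapping peak among the 16 fixed peaks with that q. With all tied CoREST2 peaks, native overlap was 0.456 (exact p = 0.109) and the fixed treatment difference -0.024. With ties in list order these were 0.414 (exact p = 0.0938) and -0.0791, and fixed overlap was 0.261 (exact p = 0.0156). Leaving out 1 library gave 0 to 1 ISX9-specific and 1 to 7 DMSO-specific regions, where fewer libraries loosen the rule. Leaving out 1 library also gave similarity differences of -0.156 to 0.00655, above 0 without ISX9 1. It gave fixed overlaps of 0.183 to 0.288 and native overlaps of 0.355 to 0.565 (exact p = 0.0312 to 0.0625). With 1 library below its control kept among 6, the p cannot go under 0.0625, so these p-values say nothing about stability. Peak number differed by -436 to -21.25, the gene-end share by -0.531 to -0.0456 (-0.923 for ends within 5 kb), native overlap between treatments by -0.582 to -0.258 and fixed overlap by -0.0663 to 0.141, all with 1 library left out except the 5 kb value. Differences from displaced peaks were above 0 in all 20 settings of each preparation. Apart from left-out libraries, the block and the planned set of the 20000 strongest, which is the set reported, the fixed call was kept in 7 of 11 settings and the native call in 6. Beyond fewer peaks or libraries the cause was not tested. Motif tests and the repeat filter were not run. Some settings gave no value: peak number in equal lists, gene ends at q 0.001, lists and gene ends on all contigs, and Fisher's test and recurrent-region lists under the block. Read depth is unknown.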

Other observations

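The chromosome-matched test in this part was set before its result was seen, and the comparison of members per library after. STAT3 peaks were unevenly spread over chromosomes. Chromosome 20 had 1.23 ± 0.316 peaks per Mb (SD, n = 7) and was the densest autosome in 6 of 7 libraries. Chromosome 14 had 0.0976 ± 0.0341 and was the sparsest autosome in 6 of 7. Chromosomes 11, 15 and 7 had 0.894, 0.833 and 0.804 peaks per Mb. The native CoREST2 list was also dense on chromosomes 11, 7 and 20 (261, 253 and 251 per Mb) and sparse on chromosome 14 (139). It was not dense on chromosome 15 (210). The fixed list was sparse on chromosome 14 (168) and not dense on chromosome 20 (203). Part of the unevenness was therefore not particular to STAT3.

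Goblet and mucin genes near DMSO STAT3 peaks were 6 of 22, a count chosen for a closer look because it passed under 1 of 3 ways of pooling libraries. Gains and losses of whole chromosomes do not account for it alone, since 0.490% of 10000 random lists with the same number of genes per chromosome had as many members near a DMSO peak, with a mean of 1.67. This test does not allow for the choice of this list out of 12. The treatment may or may not matter: the difference was -1.83 members per library (ISX9 minus DMSO, exact permutation, adjusted p = 0.857, where a single list cannot get under 0.343). The 6 genes rest on summits of 3 to 5 fragments, each in 1 library except CREB3L1, and gains of parts of chromosomes were not tested.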
